A study of Mus musculus with 28 samples.

How the data were processed

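RNA was measured in striatum, the dopamine-innervated input nucleus of the basal ganglia, from 28 C57BL/6J mice. Of these, 16 had received haloperidol, an antipsychotic that blocks dopamine receptors, and 12 had received placebo. The series describes the treatment as chronic; dose, duration and sex are not given in the sources used here. Per the labels, total RNA was made into libraries with an Illumina TruSeq RNA v2 kit in 2 batches. Batch 1 held 8 haloperidol and 8 placebo libraries and batch 2 held 8 haloperidol and 4 placebo libraries. Each library is 1 mouse, and is named here by its group and mouse number as a replicate number.

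The deposited values are FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) for RefSeq transcripts, per the file contents. Reads were aligned with TopHat2 2.0.6 to the mm9 mouse genome and quantified with Cufflinks, per the submitters' processing notes; the Cufflinks version is not given in the sources used here. Every library lists the same 30563 transcripts under 23309 gene symbols, with mm9 coordinates that are printed here as deposited. No transcript of the mitochondrial chromosome is listed. The labels call the libraries strand-specific, but whether strand was used in the quantification is not given in the sources used here, so genes that share exon bases with a gene on the other strand are uncertain. Among the genes named in the text this concerns Ppp1r1b, Arpp21, Dbp and Gabra5; Rpl34 shares 401 exon bases with a pseudogene copy on its own strand.

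Read counts are not part of the deposited values and the absolute depth is unknown, so no counting interval was computed. The ratio of coverage to FPKM is the same for all transcripts of a library and gives its depth relative to the other libraries, which ranged from 0.433 to 1.73. Cufflinks gives an interval around each FPKM. Among transcripts of FPKM 1 or more, the half-width of that interval had a median of 12.2% of the FPKM in the library with the narrowest and 22.7% in that with the widest. The sum of all FPKM ranged from 380952 to 575171. Pearson's r between libraries ranged from 0.886 to 0.988 with a median of 0.970, and 0 pairs of libraries held identical values.

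Gene FPKM was the sum over transcripts of a symbol. Genes with a mean FPKM of at least 1 over the 28 libraries were tested, which gave 12760 genes. FPKM were divided by a median-of-ratios factor per library, and the scaled FPKM are the values printed with their SD. Tests used limma 3.58.1 (lmFit and eBayes with a mean-variance trend) in R 4.3.3 on log2(scaled FPKM + 0.5), with treatment and batch as terms, 2-sided, and Benjamini-Hochberg adjustment at a threshold of 0.05. Fold changes are on the log2(value + 0.5) scale, which understates the change of low genes. The same fit gave the batch difference. A fit with a treatment-by-batch term and fits on each batch alone were added. Transcripts with a mean FPKM of at least 1 were tested likewise, and the share of a transcript within its gene as the log2 ratio of the transcript to the other transcripts of the gene.

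Before the data were examined, 32 gene lists were fixed, covering striatal neuron types, neighbouring tissues, glia, blood and pathways. The list of mitochondrially encoded genes had no member among the files' transcripts and 31 lists were tested with camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were run beside it. SPN stands for spiny projection neuron, the main neuron of the striatum. Genes named in the text were chosen by a rule fixed at the same time: up to 12 genes with the largest change past the threshold in each direction, filled up to 6 per direction by the smallest p; up to 4 members with the smallest p of each list described; a fixed set of striatal genes; and the 5 smallest p of the interaction, transcript and share tests. Drd3 was in the fixed set but lay under the minimum FPKM. Which lists are described by member was decided after values were seen (18 of the lists), which left 89 genes to be followed through the alternatives. Some genes that the rule selects are left out of the text, so the named genes are not the full selection. Genes named for the batch difference and in alternative fits, and the list tests of the batch difference, were chosen after their values were seen.

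RIN (RNA integrity number, from the labels), the FPKM sum and relative depth were compared between groups by 2-sided permutation tests with 100000 resamples, and by exact permutation tests within each batch, in Python 3.11.15 with NumPy 2.4.6 and SciPy 1.17.1. The gene and list tests were checked on simulated data made from the real libraries with treatment labels broken up and 200 of the 12760 genes changed. For the haloperidol comparison, the gene test recovered 22.4% of genes changed by 1.2-fold, 73.3% of those changed by 1.5-fold and 94.1% of those changed by 2-fold. The median share of false calls was 0% over 20 simulated sets, but 1 set gave 7302 false calls. Recovery was pooled over all 20 sets, that set included. The rates hold for 200 changed genes. With fewer changed genes the Benjamini-Hochberg adjustment is stricter, so they do not carry over to a response of few genes. With no change simulated, camera with the preset correlation called 8 of the 31 lists on average and at most 14, and with an estimated correlation it called 0.

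Alternatives fixed together with the lists were deposited FPKM without scaling, rescaling to a common sum, quantile normalization, pseudocounts of 0.1 and 1, other FPKM minimums, no batch term, RIN or the mean of the cortical neuron list as covariates, array weights, robust empirical Bayes, a Wilcoxon test stratified by batch, an adjusted p of 0.10 and leaving out each library. Alternatives chosen after seeing the data were log2 of the FPKM sum as a covariate (for the gene lists also a sum without the genes of the ribosomal protein and oxidative phosphorylation lists), leaving out the 6 libraries with RIN under 7.5, leaving out the 4 libraries with an FPKM sum over 540000, and leaving out 34 genes whose longest transcript is under 200 nt.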

Results

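Striatal RNA from 28 C57BL/6J mice was compared between 16 mice given haloperidol and 12 given placebo. The question stated by the series is how chronic haloperidol affects gene expression in the striatum. Group sizes were 8 and 8 in batch 1, and 8 haloperidol and 4 placebo in batch 2. The deposited FPKM summed to 471932 ± 60383 (SD, n = 16) in haloperidol and 451581 ± 63161 (SD, n = 12) in placebo libraries. RIN averaged 8.05 ± 0.504 (SD, n = 16) and 7.92 ± 0.554 (SD, n = 12), a difference within the spread between mice (permutation p = 0.525). Within batches the RIN difference was 0.159 in batch 1 (exact permutation p = 0.427) and -0.156 in batch 2 (exact permutation p = 0.634). The log2 relative depth differed by 0.166 over all libraries, within the spread between mice (permutation p = 0.444). In batch 2 relative depth averaged 1.196 ± 0.275 (SD, n = 8) in haloperidol and 0.733 ± 0.280 (SD, n = 4) in placebo, and its log2 differed by 0.756 (exact permutation p = 0.00808). In batch 1 the log2 difference was -0.207 (exact permutation p = 0.496).

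Anxa3, which encodes a calcium-dependent phospholipid-binding annexin, rose under haloperidol and was the only 1 of 12760 genes past the threshold. Its level was 10.5 ± 1.78 scaled FPKM (SD, n = 16) against 7.32 ± 1.91 (SD, n = 12), a log2 fold change of 0.58 (SE 0.09, limma adjusted p = 0.0152), or 1.49-fold. It lay above the placebo mean in 16 of 16 haloperidol libraries. The gene (NM_013470, 13 exons, plus strand) spans 97222404 to 97274987 of chromosome 5 in mm9. The log2 fold change was 0.45 in batch 1 and 0.77 in batch 2, and the difference between batches did not pass the test (interaction adjusted p = 0.863). The call was lost without placebo replicate 22 (adjusted p = 0.0638), without the batch term (adjusted p = 0.179), with rescaling to a common sum (adjusted p = 0.170) and with a stratified Wilcoxon test (adjusted p = 0.479).

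The genes next in line did not pass the threshold. Penk, the precursor of the enkephalin opioid peptides made by indirect-pathway neurons, measured 1088 ± 168 scaled FPKM (SD, n = 16) against 755 ± 204 (SD, n = 12), a log2 fold change of 0.57 (SE 0.11, adjusted p = 0.0825), with 16 of 16 haloperidol libraries above the placebo mean. Nts, the precursor of neurotensin, measured 25.3 ± 8.43 against 18.1 ± 8.78, a log2 fold change of 0.73 (SE 0.15, adjusted p = 0.0851). It was above the placebo mean in 12 of 16 libraries. The means and this count pool both batches, while the fold change is adjusted for batch. Nts itself differed between batches, at 15.5 ± 6.42 in batch 2 against 27.2 ± 7.65 in batch 1. The non-coding transcript 9230009I02Rik measured 2.05 ± 0.532 against 1.07 ± 0.432 (log2 fold change 0.73, adjusted p = 0.0825), near the lower end of the measured range, with a median Cufflinks interval half-width of 47.7%. Penk (NM_001002927, 2 exons, minus strand) spans 4060683 to 4065592 of chromosome 4, and Nts (NM_024435, 4 exons, minus strand) spans 101944390 to 101953052 of chromosome 10. Within batches, the log2 fold change of Penk was 0.54 in batch 1 and 0.63 in batch 2, and that of Nts was 0.48 and 1.11 (interaction p = 0.0338 before and 0.863 after adjustment). Further genes with higher values were 2410018M08Rik (log2 fold change 0.29, adjusted p = 0.121) and the keratin gene Krt77 (0.44, adjusted p = 0.122). Among genes with lower values none passed the threshold. The smallest p belonged to Shq1, a box H/ACA ribonucleoprotein assembly factor, at 1.43 ± 0.253 against 1.89 ± 0.290 scaled FPKM (log2 fold change -0.33, adjusted p = 0.188), followed by the secreted glycoprotein gene Stc1 (-0.46, adjusted p = 0.374), Spred3 (-0.26), Tmem50b (-0.16), Sfxn1 (-0.20) and Hsd17b12 (-0.17). Of all genes, 803 had an unadjusted p under 0.05, 436 higher and 367 lower, where 638 would be the average by chance. Genes vary together between libraries, so counts by chance can lie far from that average. No splits were run for this count, and no excess over chance is read from it. Leaving out each library, the number at an unadjusted p under 0.05 went from 467 (without placebo replicate 32) to 1805 (without haloperidol replicate 17). It was 2836 with RIN as a covariate, 1675 with array weights, 986 with log2 of the FPKM sum and 437 without the batch term. With RIN as a covariate 5 genes passed, with log2 of the FPKM sum 7 passed, and without the 6 libraries of RIN under 7.5 there were 4; Anxa3 and Penk were among them each time.

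**Figure D1:**
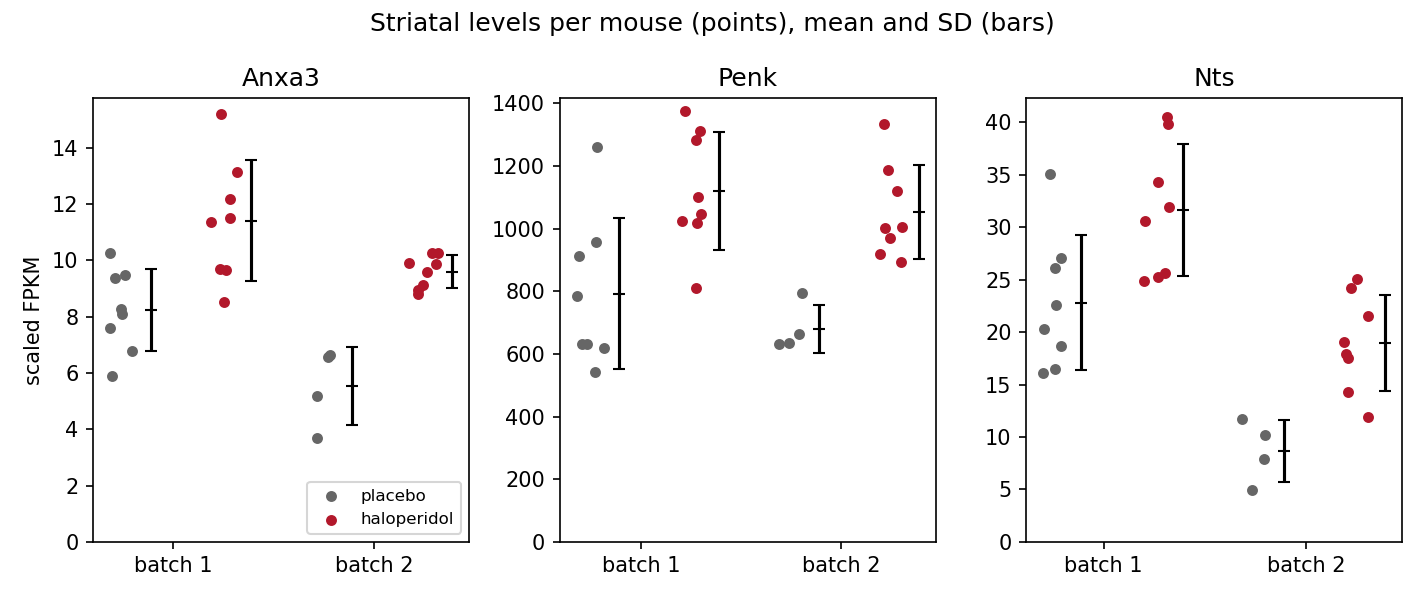
Scaled FPKM per mouse (y axis) for Anxa3, Penk and Nts in placebo (grey) and haloperidol (red) libraries of each batch (x axis), with bars for the mean and SD. Anxa3 and Penk lie above the overall placebo mean in 16 of 16 haloperidol libraries, and Anxa3 alone passed the threshold (adjusted p = 0.0152).

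In the neuropeptide list, 0 of 19 members passed the threshold over all genes, and 3 (Penk, Nts and Cartpt) were higher when adjusted over the list alone. Cartpt, the precursor of the CART peptides, measured 36.0 ± 21.8 scaled FPKM (SD, n = 16) against 22.9 ± 15.9 (SD, n = 12), a log2 fold change of 0.83 (SE 0.25, adjusted p = 0.565 over all genes and 0.0149 over the list). Tac1, the substance P precursor of direct-pathway neurons, measured 116 ± 18.6 against 139 ± 35.8 (log2 fold change -0.21, adjusted p = 0.565), and Pdyn, the dynorphin precursor of the same neurons, 16.8 ± 9.93 against 18.9 ± 9.22 (log2 fold change -0.21, adjusted p = 0.709; 0.17 with log2 of the FPKM sum in the model). The list as a whole was not called (camera adjusted p = 0.122). In the model with log2 of the FPKM sum, Penk, Nts and Cartpt were again higher when adjusted over the list alone, and Npy, Vgf and Sst were lower, at log2 fold changes of -0.30, -0.17 and -0.18. Without that term these were -0.09, -0.07 and 0.04, and the 3 genes were named after their values were seen.

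The indirect-pathway list had Penk higher and 0 lower of 8 members when adjusted over the list alone, and the others did not move with it. Drd2, the dopamine receptor of these neurons and the main target of haloperidol, measured 79.2 ± 17.8 scaled FPKM (SD, n = 16) against 71.7 ± 17.3 (SD, n = 12), a log2 fold change of 0.16 (SE 0.13, adjusted p = 0.565). The adenosine receptor gene Adora2a was at 91.2 ± 18.5 against 86.2 ± 21.5 (log2 fold change 0.10, adjusted p = 0.637). The log2 fold changes of Sp9 and Gpr52 were 0.10 and -0.69. In the direct-pathway list, 1 of 8 members, Sfxn1, was lower when adjusted over the list alone (24.0 ± 2.54 against 28.0 ± 2.83, log2 fold change -0.20, below the placebo mean in 15 of 16 libraries). Drd1a, the dopamine receptor of that pathway, measured 33.3 ± 8.84 against 39.1 ± 8.85 (log2 fold change -0.26, adjusted p = 0.565). Eya1 had a log2 fold change of -0.19. Neither list was called as a whole (camera adjusted p = 0.263 for the indirect and 0.0959 for the direct pathway), except that the direct-pathway list was called without the 4 libraries with an FPKM sum over 540000. Of the 17 general SPN genes 0 passed, and the median log2 fold change was -0.04 (0.04 with log2 of the FPKM sum in the model). Ppp1r1b, which encodes the phosphoprotein DARPP-32 downstream of dopamine receptors, measured 954 ± 208 against 916 ± 254 (log2 fold change 0.11; -0.08 with quantile normalization), and Gng7 had a log2 fold change of 0.21, Actn2 0.25, Rgs9 0.25 and Arpp21 -0.22.

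**Figure D2:**
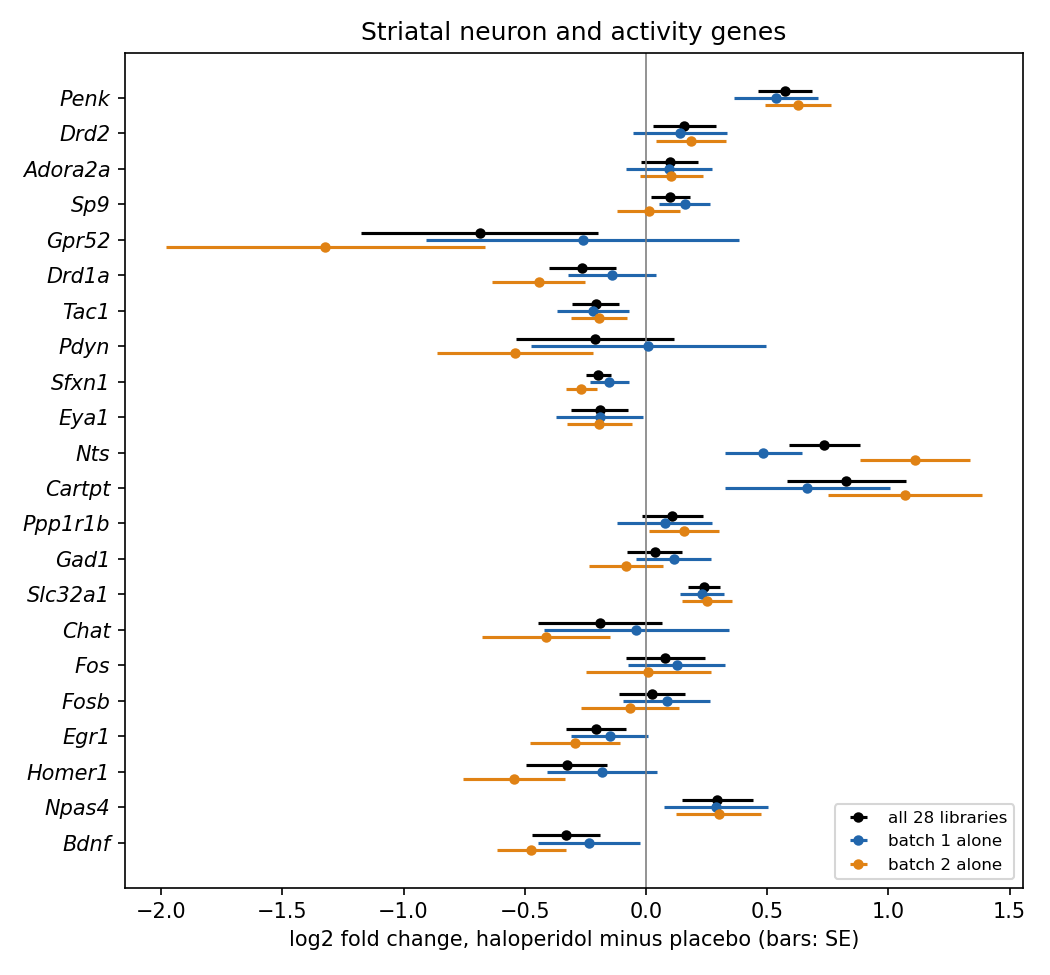
Log2 fold changes of haloperidol minus placebo (x axis) with SE bars for genes of striatal neurons and of neuronal activity (y axis), from all 28 libraries and from each batch alone. Penk stands at 0.57 over all libraries while Drd2 and Adora2a are at 0.16 and 0.10, and Fos and Fosb are at 0.08 and 0.02.

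In the dopamine and cAMP signalling list, 0 of 21 members passed over all genes or over the list alone (camera adjusted p = 0.915). Th, tyrosine hydroxylase, had a log2 fold change of 0.27 and Prkar2b, a regulatory subunit of protein kinase A, -0.16. Among GABA synthesis and receptor genes, Slc32a1, the vesicular GABA transporter, was higher when adjusted over the list alone (93.1 ± 10.5 against 80.3 ± 11.1 scaled FPKM, log2 fold change 0.24, SE 0.07, adjusted p = 0.0216 over the list and 0.540 over all genes). Gad1 measured 151 ± 32.7 against 144 ± 25.8 (log2 fold change 0.04; -0.05 with rescaling to a common sum and -0.05 with quantile normalization), while the receptor subunits Gabra5 and Gabrb2 had log2 fold changes of -0.16 and -0.22. This list was called lower by camera (adjusted p = 0.0147), with 16 of 19 members below 0, and was not called with an estimated correlation (adjusted p = 0.780). Its median went from -0.16 to -0.04 and the call was lost with log2 of the FPKM sum in the model (adjusted p = 0.721), and Gad1 was higher beside Slc32a1 when adjusted over the list alone. Of 34 glutamate receptor and scaffold genes 0 passed (camera adjusted p = 0.0959; the list was called without the 6 libraries of RIN under 7.5 and without the 4 with an FPKM sum over 540000), with log2 fold changes of -0.33 for Grin2b, 0.14 for Camk2b, 0.15 for Grin2d and -0.22 for Grm7.

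Activity-regulated immediate early genes gave 0 of 19 past the threshold, over all genes or over the list alone (camera adjusted p = 0.873). Fos measured 9.99 ± 3.23 scaled FPKM (SD, n = 16) against 9.22 ± 2.31 (SD, n = 12), with a log2 fold change of 0.08 (-0.01 with rescaling to a common sum). Fosb was at 3.72 ± 1.19 against 3.72 ± 0.927 (log2 fold change 0.02, -0.06 with rescaling), and Egr1 at 90.7 ± 23.6 against 102 ± 15.6 (log2 fold change -0.21). Homer1, Bdnf, Egr2 and Npas4 had log2 fold changes of -0.33, -0.33, -0.33 and 0.29.

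Genes of sterol synthesis and uptake gave 0 of 24 past the threshold over all genes, and the list was not called (camera adjusted p = 0.263), with a median log2 fold change of 0.05. Its enzymes went both ways. Hsd17b7, a reductase of cholesterol synthesis, measured 2.25 ± 0.854 scaled FPKM (SD, n = 16) against 2.68 ± 1.07 (SD, n = 12), a log2 fold change of -0.29 (adjusted p = 0.565). Mvk, mevalonate kinase, had a log2 fold change of 0.36 (adjusted p = 0.565).

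Camera called 6 of the 31 lists, and 0 of the calls held with an estimated correlation (0 lists at an unadjusted p under 0.05). Fry, which tests whether the genes of a list move one way, called 0 lists (1 at an unadjusted p under 0.05). Cytosolic ribosomal protein genes had a median log2 fold change of 0.24 with 77 of 79 above 0 (adjusted p = 1.86e-09, and adjusted p = 0.780 with an estimated correlation), and included Rpl34, Rps2, Rpl4 and Rpl7 at 0.98, 0.28, 0.21 and 0.18. Oxidative phosphorylation genes had a median of 0.16 with 71 of 76 above 0 (adjusted p = 5.5e-06, and adjusted p = 0.780 with an estimated correlation), with Ndufa1 at 0.29, Atp5a1 at 0.06 (-0.03 with rescaling to a common sum), Sdhc at 0.10 and Ndufb4 at 0.20. With log2 of the FPKM sum in the model these medians were -0.0022 and -0.026. The ribosomal call was lost (adjusted p = 0.937) and oxidative phosphorylation was called in the opposite direction, lower (adjusted p = 0.00761, and adjusted p = 0.901 with an estimated correlation). Heat shock genes had a median of -0.11 with 9 of 12 below 0 (adjusted p = 0.00463, and adjusted p = 0.780 with an estimated correlation). The chaperone genes Hsph1, Hsp90aa1 and Hspa1b and the co-chaperone gene Chordc1 had log2 fold changes of -0.22, -0.14, -0.34 and -0.25. Interferon response genes had a median of 0.18 with 11 of 11 above 0 (adjusted p = 0.0147, and adjusted p = 0.780 with an estimated correlation), including Irf9 at 0.18, Oasl2 at 0.22, Ifit3 at 0.27 and Isg15 at 0.39. The interferon call was lost with log2 of the FPKM sum in the model (median 0.07, adjusted p = 0.210). No member of these 4 lists passed the threshold, over all genes or over the list alone, in the model with treatment and batch. With log2 of the FPKM sum added, the heat shock genes Hspe1 and Hsph1 were lower when adjusted over the list alone, and Hspe1 also over all genes (log2 fold change -0.27, adjusted p = 0.0287, against -0.10 and 0.669 without it). Hspe1 was named after its values were seen.

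**Figure D3:**
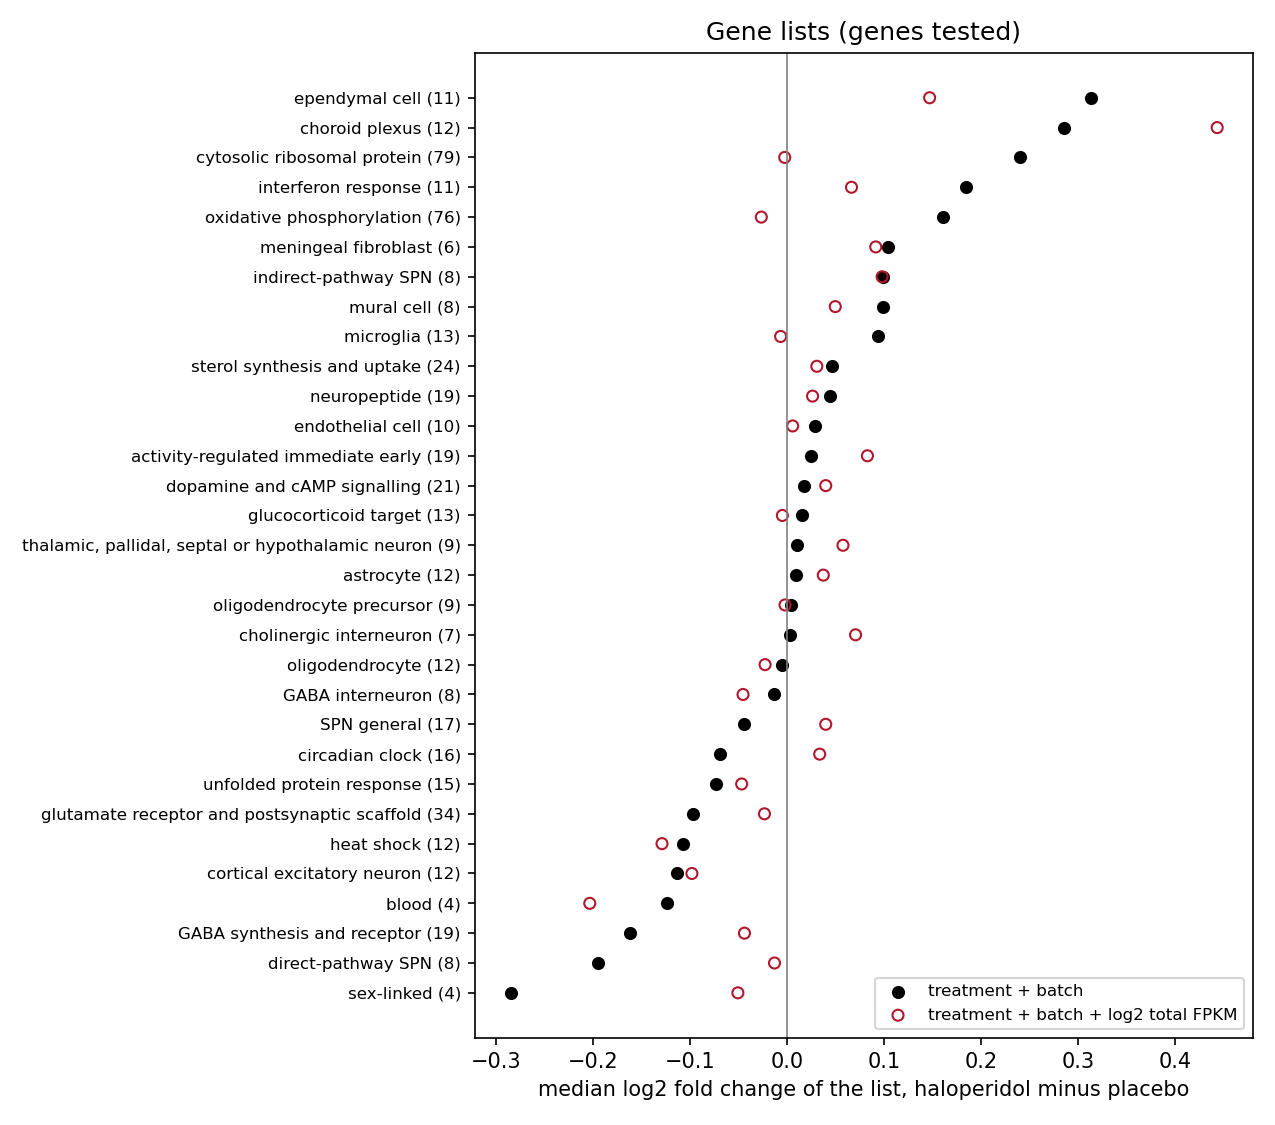
Median log2 fold change of haloperidol minus placebo (x axis) of each of the 31 gene lists (y axis, with the number of genes tested) from the model with treatment and batch (filled) and with log2 of the FPKM sum added (open). The ribosomal protein median goes from 0.24 to -0.0022 and the oxidative phosphorylation median from 0.16 to -0.026.

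Markers of neighbouring tissue and other cell types were compared in the same way, and 0 of their members passed over all genes or over the list alone. The exceptions with log2 of the FPKM sum in the model were Npy and Sst of the GABA interneuron list, lower when adjusted over the list alone. Ependymal genes, which mark cells lining the ventricle, had a median log2 fold change of 0.31 with 10 of 11 above 0 (camera adjusted p = 0.0178, and adjusted p = 0.780 with an estimated correlation). The median was -0.01 in batch 1 and 0.81 in batch 2, and with log2 of the FPKM sum in the model it was 0.15 and the call was lost (adjusted p = 0.156). The call was also lost with RIN as a covariate (adjusted p = 0.0717). Tmem212, Wdr78, Tekt1 and Ccdc153 had log2 fold changes of 0.48, -0.23, 0.37 and 0.50. The choroid plexus list had a median of 0.29 (0.00 in batch 1 and 0.70 in batch 2, camera adjusted p = 0.109). It was called higher with log2 of the FPKM sum in the model (median 0.44, adjusted p = 0.00297, and adjusted p = 0.901 with an estimated correlation) and without the 6 libraries of RIN under 7.5. Its most abundant gene, Ttr, measured 2643 ± 2255 scaled FPKM (SD, n = 16) against 1817 ± 2019 (SD, n = 12), a log2 fold change of 0.83 (SE 0.73, adjusted p = 0.570) that lay within the spread between mice. Folr1, Clic6 and Sostdc1 had log2 fold changes of 0.82, 0.36 and 0.48. Cortical excitatory neuron genes had a median of -0.11 (camera adjusted p = 0.117; called without the 6 libraries of RIN under 7.5), with Tbr1, Neurod6 and Nrn1 at -0.26, -0.29 and -0.20. In the cholinergic interneuron list (7 genes, median 0.00), Chat measured 2.67 ± 1.56 against 2.84 ± 1.14 (log2 fold change -0.19, and 0.09 with log2 of the FPKM sum), Slc5a7 had a log2 fold change of -0.27 (0.04 with log2 of the FPKM sum) and Isl1 0.07 (-0.01 with rescaling to a common sum). The medians were -0.01 for GABA interneuron, 0.01 for astrocyte, -0.0046 for oligodendrocyte, 0.0037 for oligodendrocyte precursor, 0.09 for microglia, 0.03 for endothelial, 0.10 for mural, 0.10 for meningeal fibroblast, -0.12 for blood and 0.01 for thalamic, pallidal, septal or hypothalamic neuron genes, none of them called. Median and mean differed in sign for the immediate early, dopamine and cAMP, cholinergic interneuron, astrocyte, oligodendrocyte precursor, glucocorticoid and endothelial lists. The direction of the test differed from the sign of the median for the immediate early, oligodendrocyte precursor, endothelial and GABA interneuron lists. The remaining lists, also not called, had medians of -0.07 (unfolded protein response), -0.07 (circadian clock, with Arntl at -0.30, Gm129 at 0.22, Dbp at 0.24 and Clock at -0.36), 0.02 (glucocorticoid targets) and -0.28 (sex-linked genes, 4 tested).

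Whether haloperidol acted differently in the 2 batches was tested by the interaction, which limma called for 0 of 12760 genes, with 206 at an unadjusted p under 0.05 (167 with RIN as a covariate and 413 with log2 of the FPKM sum). The smallest p belonged to Etfa, an electron transfer flavoprotein subunit, with log2 fold changes of -0.15 in batch 1 and 0.37 in batch 2, followed by Slc25a45 (-0.11 and 0.77), Zdhhc22 (0.28 and -0.45), Mthfs (-0.04 and 0.86) and Tsku (-0.08 and 0.76), all at an adjusted p of 0.863. Fitted alone, batch 1 gave 0 genes past the threshold and 96 at an unadjusted p under 0.05. Batch 2 alone gave 0 and 2150, the latter between 796 (without placebo replicate 32) and 4588 (without haloperidol replicate 25) when each library was left out. Which batch had more depended on the covariates: with RIN added the numbers were 3160 in batch 1 and 1753 in batch 2, and with log2 of the FPKM sum 566 and 732, with 0 genes past the threshold throughout. For the gene lists, camera called 7 interactions (ribosomal protein, oxidative phosphorylation, ependymal, oligodendrocyte, GABA, choroid plexus and glutamate genes), and 0 with an estimated correlation.

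The batches themselves differed in more genes than the treatment groups did. In the same model, 52 genes passed the threshold between batch 2 and batch 1, 15 higher and 37 lower in batch 2 (32 genes without scaling, 6 with RIN as a covariate, and 119 with log2 of the FPKM sum, 33 higher and 86 lower). Insig1, which holds back sterol synthesis when sterols are plentiful, measured 33.6 ± 2.82 scaled FPKM in batch 2 (SD, n = 12) against 22.4 ± 2.95 in batch 1 (SD, n = 16), a log2 fold change of 0.59 (SE 0.06, limma adjusted p = 8.6e-06), and lay above the batch 1 mean in 12 of 12 libraries. Nts was lower in batch 2, at 15.5 ± 6.42 against 27.2 ± 7.65 (log2 fold change -0.99, adjusted p = 0.000824). Insig1 and Nts remained past the threshold with RIN as a covariate (adjusted p of 0.000579 and 0.0306). These genes were chosen after their values were seen.

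At the level of transcripts, 1 of 15324 passed, the only transcript of Anxa3 (log2 fold change 0.58, adjusted p = 0.0252). The transcripts of Penk, 9230009I02Rik and Nts followed at an adjusted p of 0.130, and NM_001161422 of Ikbkg, a regulatory subunit of the kinase complex that activates NF-kappaB, had a log2 fold change of 1.56 (adjusted p = 0.236). Transcript shares within genes were tested for 4644 transcripts of 1959 genes, and limma called 0, with 222 at an unadjusted p under 0.05 (523 with RIN as a covariate and 230 with log2 of the FPKM sum). The smallest p again belonged to NM_001161422 of Ikbkg, which made up 60.9 ± 31.02% of the gene's FPKM in haloperidol (SD, n = 16) and 22.6 ± 32.7% in placebo libraries (SD, n = 12; adjusted p = 0.725). Transcripts of Phyhd1, Itsn2 and Pfdn4 followed at the same adjusted p.

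The largest axis of variation between libraries was not the treatment. The first principal component of the log2 values held 58.8% of the variance and followed the FPKM sum (Pearson's r = 0.992, Spearman's rho = 0.981, permutation p = 1e-05 for both, the smallest the resamples can give; r = 0.9903 without the 2 libraries farthest from the median). Within batches that r was 0.997 and 0.979. Its r with RIN was -0.719 (rho = -0.721, permutation p = 3e-05 and 5e-05, adjusted p = 9e-05 over 12 relations), and -0.718 without the 2 farthest libraries. In batch 1 it was -0.848 (permutation p = 4e-05) and in batch 2 -0.524 (permutation p = 0.0807; -0.224 without the 2 farthest libraries), so the relation with RIN did not pass in batch 2 and rested there on those libraries. The difference between haloperidol and placebo libraries on this component was within the spread between mice (permutation p = 0.352, and 0.354 when permuted within batch; exact permutation p = 0.711 in batch 1 and 0.0970 in batch 2). The component and the FPKM sum come from the same values and are not independent measures. Its r with log2 relative depth was -0.313 (rho = -0.305, permutation p = 0.105 and 0.114, adjusted p = 0.157; -0.364 without the 2 farthest libraries), with -0.555 in batch 1 (permutation p = 0.0272, adjusted p = 0.0545) and 0.0293 in batch 2 (permutation p = 0.928). Its r with log2 Ttr was -0.0824 (rho = 0.129, permutation p = 0.682 and 0.514, adjusted p = 0.744; 0.246 without the 2 farthest libraries), with -0.198 in batch 1 (permutation p = 0.471) and 0.364 in batch 2 (permutation p = 0.242).

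**Figure D4:**
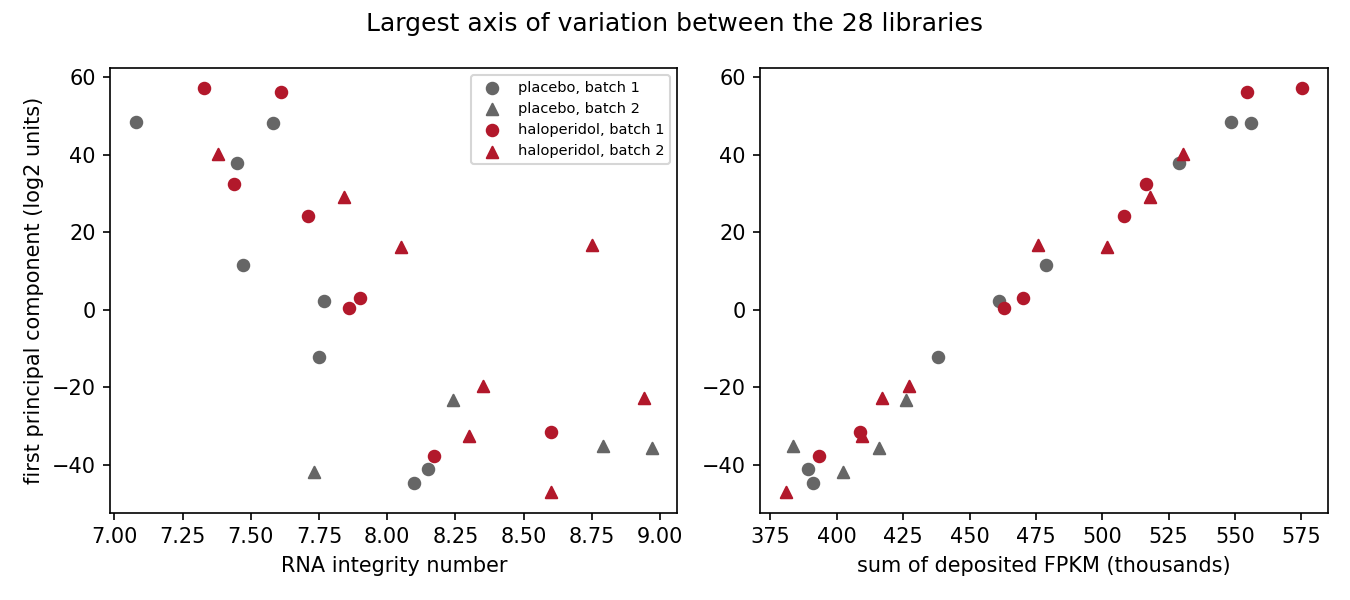
First principal component of the 28 libraries (y axis, log2 units) against RIN (left) and the sum of deposited FPKM (right), with colour for group and marker for batch. The component follows the FPKM sum with r = 0.992 and RIN with r = -0.719, and the treatment groups overlap.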

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

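Alternatives with log2 of the FPKM sum as a covariate (whole or without 2 lists), without low-RIN or high-FPKM-sum libraries, and without genes under 200 nt were chosen after seeing the data; the others were fixed before. Anxa3 was higher in 46 of 46 alternatives and past the threshold in 42 of them (log2 fold change 0.50 to 0.64, adjusted p 0.000244 to 0.479). Penk was higher in 46 of 46 and past the threshold in 7, and Nts in 46 of 46 and in 2. The haloperidol comparison called 0 genes when rescaled to a common sum (531 at an unadjusted p under 0.05), 0 with no batch term (437), 0 with the stratified Wilcoxon test (784), 2 with the cortical list mean added, 4 at an adjusted p of 0.10, 4 without RIN under 7.5, 5 with RIN added, 7 with array weights and 7 with total FPKM added. Leaving out each library gave 0 to 4 genes: 0 without placebo replicate 22, 4 without placebo replicate 12 (with Penk, Nts and 9230009I02Rik), and 2 without haloperidol replicate 5 or haloperidol replicate 23. The batch comparison called 32 genes with FPKM as deposited, 6 with RIN added and 119 with total FPKM added. Transcripts gave 2 calls with RIN added and 3 with total FPKM added. Gene lists gave 0 calls with the correlation estimated, 0 with fry and 3 with total FPKM added (heat shock and oxidative phosphorylation lower, choroid plexus higher), and the same 3 with total FPKM summed without the ribosomal protein and oxidative phosphorylation lists. They gave 5 with RIN added (ependymal lost), 9 without RIN under 7.5 (cortical, choroid plexus and glutamate gained) and 8 without FPKM sums over 540000 (glutamate and direct-pathway gained). The interaction, both within-batch comparisons and transcript shares stayed at 0 calls under every alternative run, leave-one-out fits of the interaction and of batch 2 included. The RIN difference was 0.129, and 0.0328 adjusted for batch. The cause of these shifts was not tested.

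Of 89 genes followed, 78 kept their direction in every alternative, and 34 of 4063 pairs of gene and alternative changed sign. None of the genes that did was called under any alternative. Rescaled to a common sum, the log2 fold changes were -0.00556 (Fos), -0.0579 (Fosb), -0.0548 (Gad1), -0.0135 (Isl1), -0.0275 (Atp5a1) and -0.0294 (Etfa). With quantile normalization they were -0.0456 (Gad1), -0.0818 (Ppp1r1b), -0.0562 (Atp5a1) and 0.00903 (Zdhhc22). With no batch term they were -0.0194 (Fosb) and 0.00563 (Zdhhc22), and with the cortical list mean added -0.00254 (Isl1) and 0.0251 (Zdhhc22). For the stratified Wilcoxon test the values were -0.0245 (Fosb) and 0.0146 (Zdhhc22). That test estimates no fold change. Its values are the sizes from the model with treatment and batch, given the sign of the rank statistic, so only the sign differed. With total FPKM added the log2 fold changes were 0.165 (Pdyn), 0.0948 (Chat), 0.0361 (Slc5a7) and 0.0221 (Zdhhc22). Leaving out each library gave -0.0247 (without placebo replicate 16) to 0.0844 (without haloperidol replicate 19) for Fosb, -0.00494 (without haloperidol replicate 13) to 0.0685 (without placebo replicate 32) for Gad1, and -0.0726 (without placebo replicate 12) to 0.0565 (without placebo replicate 22) for Zdhhc22. The cause of these reversals was not tested.

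No paired analysis was possible because mouse numbers are not shared between the groups. Depth limits low genes: the Cufflinks half-width was 47.7% for 9230009I02Rik and 19.3% for Anxa3, against 2.09% for Penk.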

Other observations

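The list tests between batches and the tests of the FPKM-sum gradient, of indirect-pathway RNA, of the first principal component and of the list count among splits were chosen after the results were seen, and the other splits before. Beyond the treatment, sterol genes stood out between the batches. Of 24 genes of sterol synthesis and uptake, 7 were higher in batch 2 and 0 lower (Insig1, Sc4mol, Sqle, Idi1, Cyp51 and Hsd17b7 among them), out of 15 genes higher in batch 2 in all. The list was called higher with a preset correlation (adjusted p = 1.6e-07) and with an estimated one (adjusted p = 0.00787). Genes of the unfolded protein response went the other way, with 5 of 15 lower (Creld2, Xbp1, Manf, Sdf2l1 and Hspa5) and 0 higher; that list was called with a preset correlation (adjusted p = 9.67e-05) and not with an estimated one (adjusted p = 0.302). The log2 fold change was 0.33 for Sqle and -0.49 for Hspa5. Sterol synthesis and uptake was the only 1 of the 31 lists called between batches with an estimated correlation, and RIN also averaged higher in batch 2. What differed between the batches is not given in the labels, and no explanation was tested.

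In 100 splits that shuffled treatment within batch, 4 gave as many genes as the real one (1 gene), the real one included, and the highest other gave 7640. The transcript count (1) was likewise reached by 4 of 100, with 7665 as the highest other. Shuffling batch within treatment, 3 of 100 splits reached the real count of 52, with 7516 as the highest other. For these 3 counts the share of splits was under 0.05, the bound set beforehand. With 100 splits, 4 or 3 lie too near that bound to exclude chance. A count of 1 also adds little to the adjusted p of the single call. The splits that called 7516 to 7665 point to a structure among the libraries. The counts at an unadjusted p under 0.05 did not meet the bound. These were 206 for the interaction (38 of 100 splits as large, highest other 7064), 96 in batch 1 (69 of 100, highest other 6739), 2150 in batch 2 (14 of 100, highest other 9025) and 222 for transcript shares (27 of 100, highest other 1875). Nor was the bound met for the 6 called lists (69 of 100 splits, highest other 15).

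In the first pattern, the higher Anxa3, Penk and Nts, Anxa3 went from a log2 fold change of 0.58 to 0.53 and Penk from 0.57 to 0.55 with log2 of the FPKM sum in the model, and both were past the threshold (the larger adjusted p was 0.0296), which argues against that gradient as the whole cause. Nts went from 0.73 to 0.67 (SE 0.14), a fall smaller than its SE. The bound first set for Nts, an adjusted p under 0.05, was not met (0.0851 without and 0.0615 with the FPKM sum). The bound used, more than 2 SE above 0, replaced it once these values were known, so no conclusion on the gradient is drawn for Nts. A larger share of indirect-pathway neuron RNA would raise the other members of that list as well. The median of the other 7 was 0.10 (SD 0.30) and the highest 0.16, below Penk by more than its error. Penk was singled out as the highest member, so part of this gap was fixed by that choice. The values speak only against such RNA as the whole source of the Penk rise, and a smaller contribution stays open. A haloperidol effect on Anxa3, Penk and Nts may remain as a hypothesis, found and tested on the same 28 libraries.

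The second pattern is the list calls, weighed with an FPKM sum that comes from the same values as the lists and is not an independent measure. With log2 of the FPKM sum in the model the oxidative phosphorylation median went to -0.026 and the ribosomal protein median to -0.0022. They were -0.034 and -0.0087 when the sum left out the genes of both lists, 12.0% to 22.8% of it. Neither list was then called higher, which leaves the gradient between libraries as a possible source of both calls. The 2 log2 sums correlated at r = 0.997, so the second cannot show an effect beyond the lists' own share of the sum. The interferon, GABA and ependymal calls were lost as well (adjusted p = 0.210, 0.721 and 0.156), with medians that kept their sign at 0.07, -0.04 and 0.15, so the gradient as their source stays open. The heat shock median went from -0.107 to -0.129, so it did not shrink with that term, and the list was called with the preset correlation (adjusted p = 3.73e-06). That call and the other list calls of the haloperidol comparison carry little weight, because the preset correlation called 8 of the 31 lists on average with no change simulated. Of the 6 calls in the model with treatment and batch, 0 held with an estimated correlation. With log2 of the FPKM sum in the model, the heat shock list was not called with an estimated correlation (adjusted p = 0.901) or by fry (adjusted p = 0.476). Correlated members are therefore still open as a source of this call and of the others.

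The third pattern is the first principal component. It followed RIN at r = -0.719, and its loadings fell with transcript length (Spearman's rho = -0.646 across 12760 genes, which are not independent replicates). RNA integrity may therefore contribute, but the relation did not pass in the 12 libraries of batch 2, so it stays open. Relative depth (r = -0.313, 95% interval -0.615 to 0.0677) and Ttr as a marker of choroid plexus (r = -0.0824, 95% interval -0.442 to 0.30) lie too far from 1 to be the whole cause.

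A hypothesis that both batches share one haloperidol response across the transcriptome did not meet its bound, a share of splits under 0.05. The log2 fold changes fitted in each batch alone correlated across genes at r = 0.340, and 21 of 100 splits reached that value (highest other 0.829). With log2 of the FPKM sum in each model, r was 0.0246 and 46 of 100 splits reached it (highest other 0.240). Genes are not independent replicates, and the batches share no libraries. Shuffled splits alone gave an r as high as 0.829, so a shared response would be hard to tell from chance here. The result does not show that the batches responded differently either, and the interaction was called for 0 of 12760 genes.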
